A study of Mus musculus with 9 samples.

How the data were processed

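RNA sequencing libraries of 4 young and 5 aged mice were taken from a single deposited table of 56980 Ensembl genes. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build mm8 were named, with no role given for either, while 52125 of the gene IDs were found in GENCODE M21. The quantifier and the annotation were not given in the sources used here, and no coordinates were used. The deposited table gave estimated counts per gene and library, not scaled to a common total, and these expected counts were rounded to whole numbers before testing. The log2 fold changes (aged over young) in the authors' deposited table came from a DESeq2 comparison, per the file headers, whose settings are not given. The p-values and adjusted p-values in the authors' deposited table came from the same comparison, and the adjustment was not named. The gene lengths in the deposited table were used for 1 test of length. The 9 TPM columns were not used, and 26623 genes had no count in any library.

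Samples were grouped by their labels, and labels call each a biological replicate. No pair of libraries was alike within sampling noise: the closest pair, young 1 and young 3, had a chi-square per gene of 15.3. Library totals of 19804883 to 23548594 estimated counts set the depth, and counting error is included in the dispersion of the fits. Ages and numbers of replicates were copied from the labels.

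The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term, TMM factors, filterByExpr with its minimum count of 10 and total of 15, non-robust dispersions, and Benjamini-Hochberg adjustment over 16576 genes with a threshold of 0.05. Printed levels are mean CPM with TMM factors ± SD, except for Xist and the Y-linked genes, which are counts. Log2 values per library used a prior count of 2. Biological coefficients of variation were 0.464 in the group-only fit and 0.287 with the library set as a term. Each adjusted p called edgeR is from this test, two-sided.

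Gene lists of cell type markers and pathways, 40 in all, were fixed before the data were examined, as were the group-only test, the rule for named genes and the alternatives, except those named below. The 39 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. Members were also adjusted over the list alone. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Mean list scores per library were compared by exact permutation over all samples and within the library sets. Annotation terms of the deposited table with 10 to 500 tested members were tested with the hypergeometric test.

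The text names Ntn4 and any other netrin list member that passes, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM and groups that do not overlap, up to 4 members with the smallest adjusted p of each list described, and Xist and the Y-linked genes. The rule for the largest changes named 0 genes, since 0 genes passed. Some genes that the rule names are not reported here. Genes with the largest changes under the library set term were chosen after their values were seen.

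The library set (young 4, aged 3 and aged 4 against the other 6 libraries) was defined by the largest gap in the ribosomal protein share. The Y-linked term came from Xist and Y-linked counts. Both the set and this term were chosen after the data were seen. Alternatives were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, totals), robust dispersions, other low-count filters, each library left out, a surrogate variable from sva 3.50.0, removal of gene classes, and subsets of libraries. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

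The tests were tried on simulated counts for the 16576 genes, with the libraries' means and sizes and 200 changed genes. The group-only fit recovered 4 of 100 genes changed 2-fold and 51 of 100 changed 4-fold, and called 6 of 16376 unchanged genes. The fit with the set term recovered 37 of 100 and 78 of 100, and called 4 unchanged genes. Of 40 random lists 0 were called, and the shifted list was called. Simulated genes were drawn independently, whereas members of real lists correlated (estimated at 0.662 for erythroid markers). The random lists therefore do not show how often camera calls correlated lists. The group-only simulation also held no difference between the library sets. Coordinates, isoforms and reads were not analysed here.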

Results

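Bulk RNA was sequenced from 9 wild-type C57BL/6 mice, 4 of them young (3 months old) and 5 aged (20 months old), each labelled a biological replicate. The labels gave the tissue as bone marrow, and the extraction protocol named homogenised trabecular bone, so the libraries could hold both marrow and bone cells. The young libraries held 23336827, 20120991, 21939706 and 20957047 estimated counts, and the aged libraries 19804883, 19843882, 19840431, 22367653 and 23548594. The comparison asked which transcripts differed with age, in a series about sensory nerves and netrin-4, a secreted axon guidance protein.

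Transcripts that mark sex and a split of the libraries crossed this design. Xist, the RNA of the inactive X chromosome, had 21724, 15847, 7909 and 8179 counts in aged 1 to 4, and 8, 4, 8, 1 and 9 counts in young 1 to 4 and aged 5. The Y-linked gene Ddx3y had 888 to 1721 counts in the young libraries and 1640 in aged 5, and 0 counts in aged 1 to 4. Eif2s3y, also Y-linked, had 1466 to 1912 counts in the young libraries, 1205 in aged 5 and 0 in aged 1 to 4. These values went against the stated female sex in 5 libraries, the 4 libraries labelled young and aged 5, so that age and sex chromosome transcripts differed together in all aged libraries but 1. Separately, young 4, aged 3 and aged 4 differed from the other 6 libraries. Ribosomal protein genes took 5.63% to 6.54% of the counts in these 3 and 2.86% to 3.08% in the other 6. Correlations of log2 values across genes were 0.922 to 0.956 within the 3, 0.941 to 0.986 within the 6 and 0.853 to 0.913 between them. Aged 5 correlated at 0.969 to 0.977 with young 1 to 3 and at 0.961 and 0.958 with aged 1 and aged 2, while young 1 to 3 correlated with each other at 0.983 to 0.986 and aged 1 with aged 2 at 0.964. Comparisons within the 3-library set (1 young library) and of young 1 to 3 with aged 5 (1 aged library) have a single library in an arm, assumed to vary like the others, so lists are given there as means, without a test. Values with this library set as a term in the fit, chosen after the data were seen, stand beside the group-only values below.

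**Figure D1:**
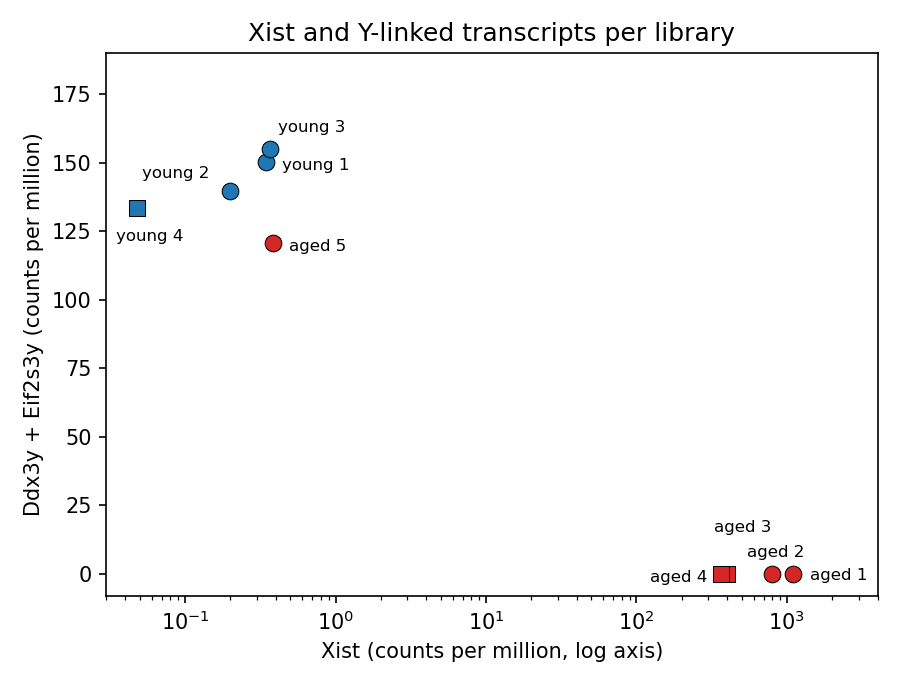
Summed CPM of Ddx3y and Eif2s3y against Xist CPM (log axis) in each library, with circles for the 6-library set, squares for the 3-library set, blue for young and red for aged. Aged 5 lay with the 4 young libraries, and aged 1 to 4 had 0 counts of both Y-linked genes.

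In aged bone, transcripts of red cell precursors, dividing cells and bone-forming cells were lower as groups, and those of plasma cells, T and NK cells and monocytes were higher. The median log2 fold change (aged over young, n = 4 and 5) was −1.23 over 21 erythroid markers, −0.46 over 27 cell division genes, −0.57 over 25 osteoblast markers, 1.30 over 22 plasma cell genes and 0.88 over 27 T and NK cell markers. Of 39 gene lists tested, 17 passed camera with a preset correlation, 7 of them higher and 10 lower in aged libraries. With an estimated correlation 0 of the 17 calls held, the smallest adjusted p being 0.142, and fry called 1 list, the monocyte and dendritic cell markers (adjusted p = 0.04996). With the library set term 11 lists were called, of which 0 held with an estimated correlation (smallest adjusted p 0.299) and fry called 2. Within the 6-library set 12 lists were called by camera with the preset correlation, the only list test run there. Adjusted p-values of lists within that set all come from it and carry the same limit. Exact permutation of list scores called 0 of the 39 lists (smallest adjusted p 0.248). Its p cannot fall below 0.00794 with 126 arrangements, so after adjustment over 39 lists it could hardly call any. Before adjustment its p was 0.0159 for monocyte and for T and NK cell, 0.0238 for senescence, 0.0317 for erythroid and for cell division and 0.0397 for plasma cell lists. The remaining lists had 0.0635 or more. Other splits of the libraries often gave as many camera calls: 26 of 100 splits, the real one included, gave at least 17, and with the set term 51 of 60 gave at least 11. Between young 1 to 3 and the single library aged 5, all with Y-linked transcripts, the mean log2 fold change was −2.07 for B cell progenitor, 1.17 for plasma cell, −0.88 for erythroid, −0.68 for osteoblast, 0.49 for T and NK cell, −0.32 for cell division and 0.28 for monocyte lists. The adipocyte and interferon lists turned there (−0.36 and −0.45), and the senescence list was near 0 (−0.02).

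No single gene passed the group-only test. The edgeR quasi-likelihood test called 0 of 16576 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.255, while 1457 genes had an unadjusted p under 0.05 (688 higher, 769 lower) against 829 expected by chance. Limma-voom called 0 genes and DESeq2 called 311. With the library set term, edgeR called 319 genes, 102 higher and 217 lower. Their smallest adjusted p was 0.0405, a value that many genes below share through the adjustment, so all 319 lay close to the threshold of 0.05. The count depended on single libraries: it was 0 without young 1, 2 or 3 or aged 1 or 4, 2 without young 4, 1 without aged 2, 1633 without aged 3 and 712 without aged 5. Where tested, the 319 genes kept their sign in each of these fits, which share all libraries but 1 with the full fit. With both the set and Y-linked expression as terms the count was 5, all of them immunoglobulin variable segments. In that fit aged 5 alone sets the age effect, so the low count cannot tell sex from a loss of power. All 319 genes kept their sign there, but they had been chosen with aged 5 included.

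Ntn4 (ENSMUSG00000020019), which encodes netrin-4, was lower in every aged library than in every young library. Its level was 12.1 ± 1.71 CPM (counts scaled to library size) in young (SD, n = 4) and 5.71 ± 1.05 in aged libraries (SD, n = 5), from 89 to 344 estimated counts per library. The log2 fold change was −1.08 (SE 0.22), with an edgeR adjusted p of 0.255 over all genes. A two-sided exact permutation test of Ntn4 alone gave p = 0.00794, the smallest that the 126 arrangements allow. With the library set term Ntn4 fell by 1.05 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0405), a call that was lost on leaving out any of young 1 to 4 or aged 1, 2 or 4 (adjusted p 0.0568 to 0.176 in those fits). An exact permutation of Ntn4 within the sets gave p = 0.0167, the smallest that 60 arrangements allow. Neither permutation p was adjusted over genes. Ntn4 was tested because the series is about netrin-4, and the authors' comparison of these same libraries also called it. Whether it was first picked from these libraries is not known, so these p-values are not independent support. Its log2 fold change was −1.08 within the 6-library set (edgeR adjusted p = 0.0694) and −0.90 within the 3-library set (1 young library, given without a test). Between young 1 to 3 and aged 5, the libraries of the 6-library set with Y-linked transcripts, it was −0.93 (1 aged library, given without a test).

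**Figure D2:**
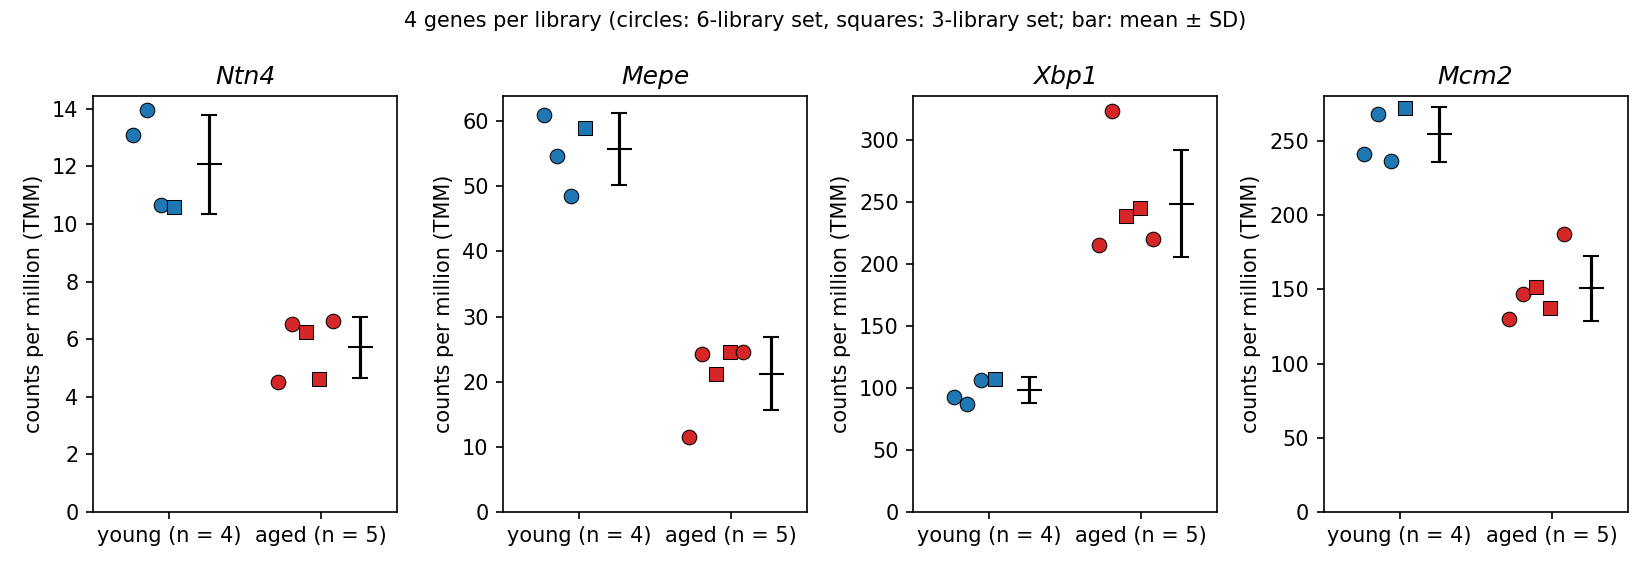
Normalised CPM of Ntn4, Mepe, Xbp1 and Mcm2 in each library, with circles for the 6-library set, squares for the 3-library set and bars for mean ± SD (n = 4 young, n = 5 aged). Ntn4 was at 12.1 ± 1.71 in young and 5.71 ± 1.05 in aged libraries, and Mepe at 55.8 ± 5.52 and 21.2 ± 5.63.

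The netrins and their receptors were lower as a list (median log2 fold change −0.43, camera adjusted p = 0.0304), and adjusted p = 0.662 with an estimated correlation. Of its 9 tested members, 4 were above 0 and 5 below. Among them 1, Ntn4, passed when adjusted over the list alone and 0 over all genes. Ntn3, another secreted netrin, was at 1.02 ± 0.0475 CPM in young and 0.471 ± 0.126 in aged libraries (edgeR adjusted p = 0.407). The list call was lost with the library set term (adjusted p = 0.200) and without young 1, young 2 or aged 4 (adjusted p = 0.0975, 0.179 and 0.297).

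Lists of nerve transcripts were not called. Camera adjusted p was 0.254 for 9 sensory neuron transcripts, 0.0865 for 13 Schwann cell markers, 0.326 for 37 other axon guidance genes, 0.179 for 10 neurotrophic factors and receptors and 0.796 for 10 neuropeptide and neurotransmitter receptors. Only 3 sympathetic neuron transcripts were measured well enough, too few for a test. Gfap, an intermediate filament gene of glia, was at 20.4 ± 3.35 CPM in young and 6.31 ± 3.22 in aged libraries (edgeR adjusted p = 0.255, and 0.0532 with the set term), and it passed over the Schwann list alone. Sema3d, a semaphorin, was at 4.41 ± 1.26 and 1.56 ± 0.488 (adjusted p = 0.267). Gfra1, a receptor for a glial neurotrophic factor, was at 7.79 ± 2.77 and 2.78 ± 1.47 (adjusted p = 0.330), and P2rx3, an ATP-gated channel of sensory neurons, at 2.00 ± 0.871 and 0.662 ± 0.474 (adjusted p = 0.420). Other members went the other way: Adrb1, an adrenergic receptor gene, was at 0.355 ± 0.263 and 2.75 ± 2.76 (adjusted p = 0.342), Gata3, of the sympathetic list, at 1.04 ± 0.242 and 2.21 ± 0.908 (0.438), Egr2, of the Schwann list, at 1.25 ± 0.367 and 2.63 ± 1.14 (0.497), and Sema3f at 3.43 ± 1.29 and 6.90 ± 3.57 (0.520).

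Bone lists were lower in aged libraries. Osteoblast markers had 21 of 25 members below 0 (camera adjusted p = 3.5e-08, and adjusted p = 0.40 with an estimated correlation), with 2 members lower when adjusted over the list alone. Sparc, a matrix glycoprotein gene, was at 891 ± 335 CPM in young and 283 ± 148 in aged libraries, and Omd (osteomodulin) at 4.98 ± 1.51 and 2.14 ± 0.474 (edgeR adjusted p = 0.299 and 0.289). Osteocyte markers had 11 of 14 members below 0 (camera adjusted p = 3.6e-04, and adjusted p = 0.313 with an estimated correlation), with 1 member lower over the list alone. That member was Mepe, a matrix phosphoglycoprotein gene of osteocytes, at 55.8 ± 5.52 and 21.2 ± 5.63 CPM (log2 fold change −1.39, SE 0.23, edgeR adjusted p = 0.255, and 0.0405 with the set term). The Wnt inhibitor genes Sost and Dkk1 were at 48.2 ± 9.35 and 22.8 ± 14, and at 7.11 ± 3.61 and 2.49 ± 1.19 (adjusted p = 0.489 and 0.342). All 9 chondrocyte markers were below 0 (median −0.87, camera adjusted p = 3.3e-04, and adjusted p = 0.40 with an estimated correlation), 3 of them past the threshold over the list alone. Within the 6-library set the mean log2 fold change was −0.64 for osteoblast (adjusted p = 0.00252), −0.29 for osteocyte (0.148) and −1.35 for chondrocyte markers (0.0288). Within the 3-library set, with 1 young library, it was −0.97, −0.61 and −1.31. Young 3 lay among the aged libraries: its mean osteoblast score (−0.23) was below those of aged 2, 3 and 5, and its chondrocyte score (−0.58) below those of aged 1, 2 and 3, while young 1 and young 2 had chondrocyte scores of 1.69 and 1.11.

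Matrix and stromal lists were called with smaller shifts. Extracellular matrix genes (median −0.19, camera adjusted p = 0.00169), fibroblast and periosteal markers (median −0.19, adjusted p = 0.0304) and Wnt pathway genes (median −0.17, adjusted p = 0.0201) were lower, each with an adjusted p of 0.662 with an estimated correlation. Over the list alone, 1 matrix gene was lower, 1 fibroblast marker was higher and 2 were lower, and 0 Wnt genes passed. Col3a1, a fibrillar collagen gene, was at 166 ± 98.8 CPM in young and 34.0 ± 22.9 in aged libraries, and Lum (lumican) at 57.6 ± 16 and 19.4 ± 7.67. Both fell with the set term, with log2 fold changes of −2.15 and −1.61 (edgeR adjusted p = 0.0437 and 0.0455). Ly6a went the other way, at 20.6 ± 7.0 and 75.6 ± 37.8 (adjusted p = 0.264). Marrow adipocyte markers were higher (median 0.46, camera adjusted p = 0.0302), and adjusted p = 0.490 with an estimated correlation, with 0 members past the threshold over the list alone. Lpl (lipoprotein lipase) was at 145 ± 24.1 and 247 ± 88.2 (adjusted p = 0.520), and the adipocyte list had a mean log2 fold change of −0.36 between young 1 to 3 and the single library aged 5. These 4 lists lost their calls with the library set term, at an adjusted p of 0.0881 for matrix, 0.102 for fibroblast, 0.102 for Wnt and 0.0634 for adipocyte genes. They also lost them on leaving out single libraries: matrix genes without young 2 or aged 4 (highest adjusted p 0.212), fibroblast markers without young 2 or 4 or aged 1, 4 or 5 (0.225), Wnt genes without young 4 or aged 1, 4 or 5 (0.212), and adipocyte markers without young 1 or 3 or aged 2 or 3 (0.139).

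Erythroid markers were lower in aged libraries. All 21 members were below 0 (camera adjusted p = 5.3e-23, and adjusted p = 0.165 with an estimated correlation), 16 of them past the threshold when adjusted over the list alone (21 with the set term) and 0 over all genes (1 with the set term). Epb42, a gene of the red cell membrane skeleton, was at 274 ± 47.1 CPM in young and 103 ± 51.6 in aged libraries (edgeR adjusted p = 0.316). Tfrc, the transferrin receptor gene, was at 777 ± 176 and 424 ± 136 and fell by 0.97 on the log2 scale with the set term (edgeR adjusted p = 0.0405). The share of counts from hemoglobin genes was 6.98% to 21.8% in young and 0.697% to 16.1% in aged libraries. All 27 cell division genes were below 0 (camera adjusted p = 4.8e-10, and adjusted p = 0.324 with an estimated correlation), 1 of them past the threshold over the list alone. With the set term 24 of the 27 were lower over the list alone and 8 over all genes, among them Mcm2, a subunit of the replicative helicase, at 254 ± 18.3 and 151 ± 22.1, and Rrm2, a ribonucleotide reductase subunit, at 439 ± 96.1 and 264 ± 66.8 (edgeR adjusted p = 0.0405 for each). The mean log2 fold change was −1.43 and −1.08 for erythroid markers, and −0.54 and −0.39 for cell division genes, within the 6-library and 3-library sets. Aged 3 lay among young libraries of the other set: its mean erythroid score (0.614) was above those of young 1 (0.568) and young 3 (0.596). Its mean cell division score (0.175) was also above those of young 1 (0.148) and young 3 (0.147). Against young 4, the young library of its own set, aged 3 was lower in both scores, by 0.58 and 0.34.

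B cell progenitor markers were lower and plasma cell genes higher. Of 19 progenitor markers, 18 were below 0 (median −0.74, camera adjusted p = 1.2e-06, and adjusted p = 0.475 with an estimated correlation), with 0 past the threshold over the list alone. Rag1, a recombinase gene of developing lymphocytes, was at 45.7 ± 15.1 CPM in young and 11 ± 10.7 in aged libraries (edgeR adjusted p = 0.466). The progenitor list had a mean log2 fold change of −1.39 within the 6-library set (camera adjusted p = 9.4e-11 with the preset correlation, and none with an estimated one was run there). It was −0.16 within the 3-library set, where aged 3 lay above young 4. All 22 plasma cell and immunoglobulin genes were above 0 (camera adjusted p = 2.3e-18, and adjusted p = 0.165 with an estimated correlation), 13 of them past the threshold over the list alone. Xbp1 and Prdm1, transcription factor genes of plasma cells, were at 98.5 ± 10.3 and 249 ± 43.5, and at 4.07 ± 1.1 and 16.1 ± 7.77. Both rose with the set term, by 1.34 (SE 0.15) and 2.02 (SE 0.35) on the log2 scale (edgeR adjusted p = 0.0405 for each). Ighg1 was at 19.9 ± 10.1 and 331 ± 343 (adjusted p = 0.267), an uncertain value because immunoglobulin genes share near-identical sequence. The plasma cell list was higher within both sets, by a mean of 1.74 and 1.82. Aged 1 lay among the young libraries, with a mean plasma cell score of −0.77 against −0.98 to −0.43 in young. It was 0.11 above the mean of young 1 to 3, the young libraries of its own set.

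T and NK cell markers had 25 of 27 members above 0 (camera adjusted p = 4.5e-12, and adjusted p = 0.142 with an estimated correlation), 10 of them past the threshold over the list alone. Gzmk, a granzyme gene, was at 0.111 ± 0.0671 CPM in young and 4.34 ± 2.93 in aged libraries, Cd8a at 3.22 ± 0.905 and 9.34 ± 2.51, and Cd3g, of the T cell receptor complex, at 3.36 ± 0.442 and 10.9 ± 4.49. All 3 rose with the set term (edgeR adjusted p = 0.0405 for each). The list was higher by a mean of 0.97 within the 6-library set and 1.06 within the 3-library set. Monocyte and dendritic cell markers were higher (median 0.55, camera adjusted p = 0.00514, and adjusted p = 0.142 with an estimated correlation), with 1 member past the threshold over the list alone. That member was Ly6c2, a monocyte surface antigen gene, at 448 ± 59.3 and 828 ± 130, which rose by 0.89 with the set term (edgeR adjusted p = 0.0405). The mean of the monocyte list was 0.36 within the 6-library set and 0.32 within the 3-library set. Early neutrophil granule genes were higher (median 0.45, camera adjusted p = 0.0482, and adjusted p = 0.662 with an estimated correlation), with 0 members past the threshold over the list alone and no call with the set term (adjusted p = 0.102) or without any of young 1, 2 or 3 or aged 1, 4 or 5 (adjusted p 0.0509 to 0.561). Prtn3, a granule protease gene, was at 523 ± 332 and 980 ± 871 (edgeR adjusted p = 0.834).

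Interferon response genes and senescence and cytokine genes were higher over all 9 libraries. Of 29 interferon response genes 24 were above 0 (median 0.62, camera adjusted p = 2.9e-06, and adjusted p = 0.490 with an estimated correlation), 2 of them past the threshold over the list alone. These were Gbp3, a guanylate-binding protein gene, at 12.2 ± 2.30 and 32.9 ± 8.17 CPM, and Zbp1, a nucleic acid sensor gene, at 9.03 ± 1.19 and 29.2 ± 12.1 (edgeR adjusted p = 0.0405 for each with the set term). The mean log2 fold change of this list was 0.50 within the 6-library set and 0.76 within the 3-library set, and it was −0.45 between young 1 to 3 and the single library aged 5. Of 20 senescence and inflammatory cytokine genes 15 were above 0 (median 0.91, camera adjusted p = 1.7e-05, and adjusted p = 0.142 with an estimated correlation), 5 of them past the threshold over the list alone. Cdkn2a, a cell cycle inhibitor gene, was at 0.298 ± 0.050 and 9.33 ± 13.4, carried by aged 1 and aged 2 (31.3 and 13.2, against 0.245, 0.935 and 1.02 in aged 3 to 5), and Ccl8, a chemokine gene, at 0.876 ± 0.524 and 6.43 ± 5.09 (edgeR adjusted p = 0.320 and 0.335). The senescence list had a mean of 1.19 within the 6-library set (adjusted p = 0.00187), 0.45 within the 3-library set and −0.02 between young 1 to 3 and the single library aged 5. For aged 5 the mean log2 CPM of the senescence list, the measure plotted per library, lay 0.31 above young 1 to 3, so the measures differed in sign there, and the reason was not tested.

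**Figure D3:**
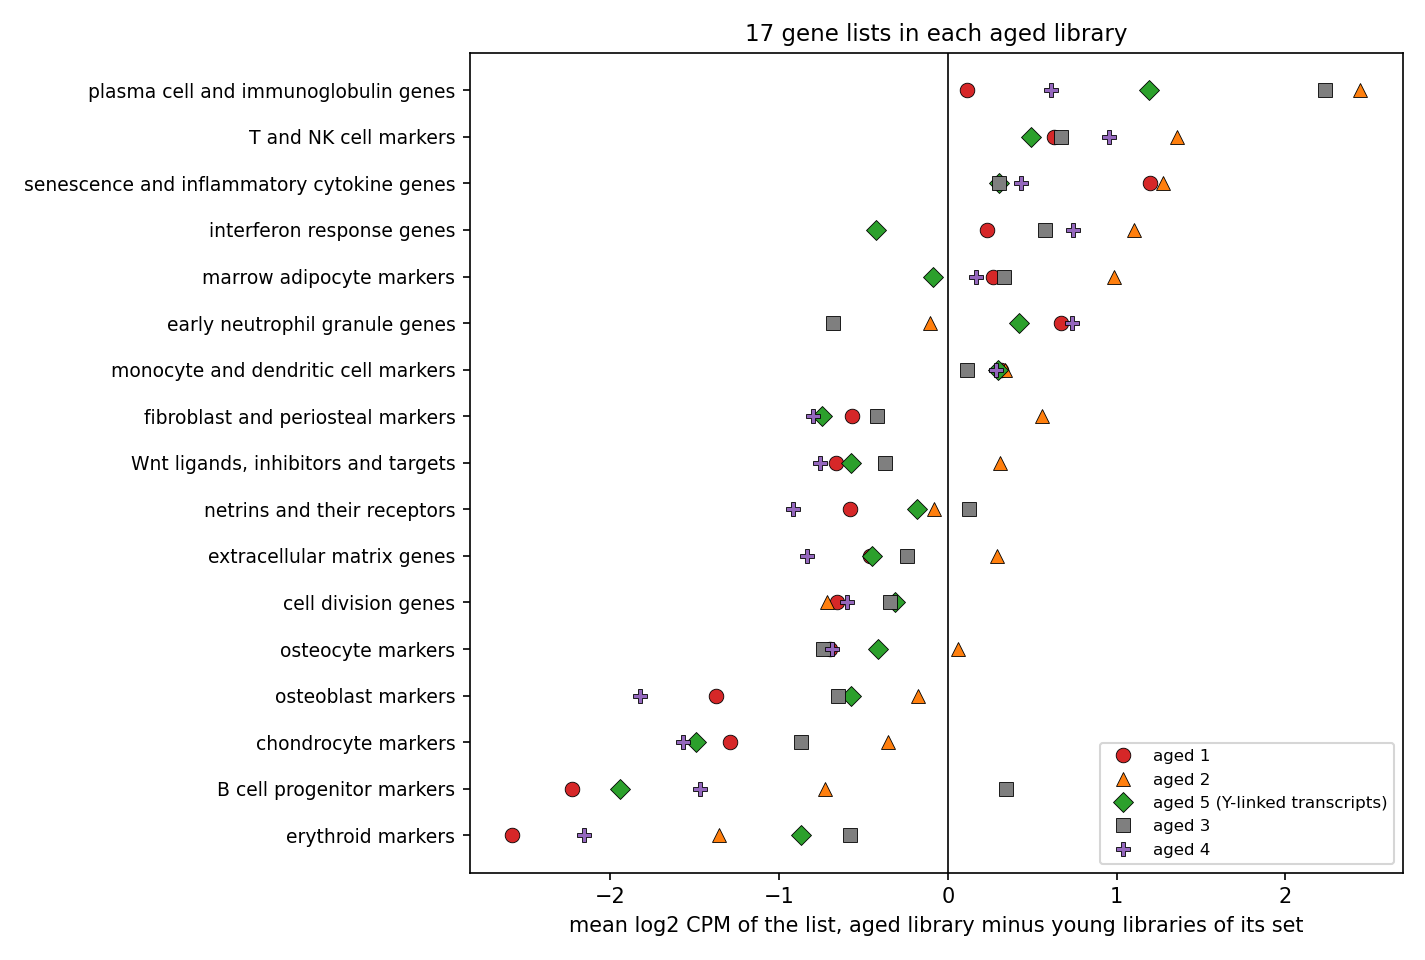
Mean log2 CPM of each of the 17 called lists in each aged library minus the mean of the young libraries of the same library set. T and NK cell, plasma cell, senescence and monocyte lists lay above 0, and erythroid, cell division, osteoblast and chondrocyte lists below 0, in all 5 aged libraries, while the interferon list lay at −0.42 in aged 5.

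The other 22 lists were not called, with a smallest adjusted p of 0.0865. Among them were osteoclast markers (camera adjusted p = 0.30), reticular stromal cell markers (0.228), endothelial markers (0.200), macrophage markers (0.107), mature B cell markers (0.219), late neutrophil markers (0.908), megakaryocyte and platelet markers (0.873) and skeletal muscle markers (0.873). The macrophage gene Fcgr1, an Fc receptor gene, was at 11.3 ± 2.16 and 25.4 ± 7.13 CPM and rose with the set term (edgeR adjusted p = 0.0471). For skeletal muscle markers and for BMP and TGF-beta genes, medians of 0.01 and 0.02 stood beside a test direction of lower.

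The authors' deposited table of a DESeq2 comparison of these libraries held 300 genes at an adjusted p under 0.05, of which 256 were also at least 2-fold, 163 higher and 93 lower in aged mice. For Ntn4 the authors' deposited table gave a log2 fold change of −1.07 and an adjusted p of 0.00201, and for Xbp1 1.35 and 5.6e-08. For Xist, a transcript that marks sex, the authors' deposited table gave 11.1 and a smaller adjusted p of 1.1e-13. Of the 256 genes in the authors' deposited table, 231 were among those tested with edgeR, 95 were also called with the library set term in the same direction, and 40 had 1 library holding over 50% of their counts.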

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

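Dixon's test marked 27 of 222 groups of library values, where chance marks about 1 in 20, or 11. All tests of explanations in this part were chosen after the results were seen, except the one of gene length, whose bounds were set before its value was computed but after ribosomal protein genes, which are short, were known to separate the libraries.

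Young 4 was far from the other young libraries in its share of hemoglobin counts (21.8%, others 6.98% to 9.15%), ribosomal protein counts (5.90%, others 2.92% to 3.04%) and the 10 highest genes (26.0%, others 11.3% to 13.2%). It also stood apart in log2 CPM of Tfrc (10.02), Rag1 (4.55), Pax5 (4.89), Zbp1 (3.44), Mcm6 (8.61), Cldn10 (2.63), Eif2s3y (7.02) and Kdm5d (3.55). Aged 3 was far from the other aged libraries in hemoglobin (16.1%, others 0.697% to 3.98%), the 10 highest genes (23.9%, others 6.12% to 10.9%), Lipe (4.23) and the number of genes with at least 1 count (17359, others 21928 to 23782). Aged 5 stood apart in Xist (−1.21), Ddx3y (5.95), Eif2s3y (5.51), Kdm5d (4.98) and Uty (3.94), and in Phospho1 (6.10) and Lpl (6.63). Single values far from their group were Ntn3 in aged 4 (−1.51), Mepe in aged 1 (3.53), Col3a1 in aged 2 (6.22), Marco in young 1 (−2.57) and the mean osteoblast score in young 3 (−0.23). Mepe, Col3a1, Ntn3, Rag1, Tfrc, Zbp1 and Lpl are named in the account of the age comparison.

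The 3-library set of young 4, aged 3 and aged 4 differed from the other 6 libraries in 8048 of 16576 genes beside age (edgeR adjusted p under 0.05). With hemoglobin, immunoglobulin and mitochondrial genes removed 8002 genes were called, so the difference was not confined to these genes. Both fits used TMM factors, which limit the pull of a few high genes. The count could therefore hardly show whether these transcripts took counts from other genes. Totals of 19840431 to 22367653 counts in the 3-library set lay within the 19804883 to 23548594 of the other 6. A bias by gene length may contribute, since Spearman's rho across genes of the set effect with length was −0.467, and the median set effect went from 0.86 in the shortest 3320 genes to −0.61 in the longest 3313; genes are not independent replicates. A different assignment of reads to genes stays open: 8 genes, Adnp among them, had 100 or more counts in each library of one set and 0 in the other, against at most 1 in other splits of 3 and 6, but 10 had been set as enough, and the bound below that was reworded after 8 was seen. No biological explanation was tested, since the labels give none for these libraries.

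Xist in aged 1 to 4 and Y-linked transcripts in the young libraries and aged 5 went against the stated female sex in 5 libraries. A swap of aged 5 with a young library that held Xist is argued against, since 0 libraries labelled young had over 100 Xist counts, and so is an exchange with young 1, 2 or 3, which correlated with each other at 0.983 or more, above the highest with aged 5 (0.977); an exchange with young 4 was not tested. Whether aged 5 came from a young mouse stays open, with bounds reworded after the values were seen, because measures disagree: its correlations were higher with young 1 to 3 (0.969 to 0.977) than with aged 1 and 2 (0.961 and 0.958, and 0.964 between those), and in genes chosen on aged 1, aged 2 and 1 young library it moved by a median of only 0.49 to 0.61 against 1.73 to 1.77 on the log2 scale. Yet it went their way in 73.2% to 83.0% of these genes (at most 59.4% for 1 young library from another), and it lay outside all 4 young libraries in Ntn4 (6.63 CPM, young 10.6 to 14), Mepe (24.6, young 48.5 to 60.9) and the mean B cell progenitor (−1.35, young 0.50 to 0.81), plasma cell (0.31, young −0.98 to −0.43) and erythroid scores (−0.21, young 0.57 to 1.20), most of them picked in a comparison that includes aged 5. RNA of both sexes mixed in aged 5 would give Xist there, which was at 0.0575% of its mean in aged 1 to 4, while male mice in 5 libraries, or an exchange with mice of another study, stay open, and no label decides between them.

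The cell type lists differed between young and aged libraries. Fewer erythroid cells as the only change would shift all other cell types alike. The shifts of 22 other cell type lists, called or not, went from −1.17 to 1.39, with 9 above 0. Because TMM scaling takes out a rise shared by most genes, the number above 0 does not bear on this. The SD of the shifts, 0.586, was larger than in other splits (exact permutation p = 0.00794, the smallest that 126 arrangements allow). Within the sets its exact permutation p was 0.0333. Unequal shifts argue against fewer erythroid cells as the whole cause, but cannot exclude them beside other changes. Sex and age could not be told apart with 1 aged library holding Y-linked transcripts: with set and Y-linked terms 13 of the 17 lists kept call and direction, B cell progenitor, plasma cell and erythroid lists among them, and the interferon and adipocyte lists turned. Age of the animals is among the open explanations, and a change in the share of cells against a change within cells was not tested.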

How the results depend on the processing

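Settings were fixed before the data were examined, except the library set, the library subsets, the Y-linked terms, the permutation of list scores and all alternatives of the fit with the set term. These were chosen after the data were seen, and those of the fit with the set term were listed only after they had been run. The count of 0 genes held under RLE, upper quartile and total scaling, limma-voom, robust dispersions, both other filters and both removals of gene classes. The 2-fold minimum and the stricter threshold can only give 0 when 0 genes pass without them. Ntn4 was lower in all 27 alternatives, from −1.15 to −0.86 on the log2 scale, with an adjusted p from 0.0019 to 1.0, past the threshold in 3. Of the 17 list calls 11 were kept with the set term and 11 in the 6-library set, not all of them the same: osteocyte markers were kept only with the set term (adjusted p = 0.0173, and 0.148 in the 6-library set) and early neutrophil genes only in the 6-library set (0.0269, and 0.102 with the set term). Leaving out 1 library gave 13 to 19 list calls; 11 of the 17 held in each of these fits, and 5 were lost without aged 4. Settings meant for normalised values were not run, because the table held counts, and DESeq2 gave no list tests.

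Counts of genes, with higher and lower ones, moved to 311 (178 and 133) with DESeq2, 257 (91 and 166) with 1 surrogate variable, 319 (102 and 217) with the set term, 2 (2 and 0) in the 6-library set, 14 (7 and 7) in the 3-library set, 1 (1 and 0) with the Y-linked term, 5 (5 and 0) with both terms and 619 (244 and 375) between young 1 to 3 and aged 5. The 2 genes of the 6-library set were the pseudogenes Rps2-ps10 and Rnps1-ps, the 1 gene with the Y-linked term was Ighv5-17, and the 5 with both terms were Ighv5-17, Igkv8-28, Ighv1-72, Ighv2-9-1 and Igkv4-63, all named after their values were seen. Leaving out 1 library gave 0 to 6 genes, 0 to 2 higher and 0 to 4 lower; the 6, without aged 5, were Xist, Ddx3y, Eif2s3y, Uty, Kdm5d and Gzmk. Fewer libraries enter the subsets, where the lone library (young 4, or aged 5) is assumed to vary like the others, and the dispersion was smaller with the set term (0.287 against 0.464); otherwise the cause was not tested. List calls moved from 17 to 11 with the set term, 0 with an estimated correlation, 1 with fry and 0 by permutation of scores. The permutation could hardly call a list, since its smallest possible p of 0.00794 was adjusted over 39 lists. Ntn4 passed the threshold with DESeq2 (−1.07), 1 surrogate variable (−1.06) and the set term (−1.05).

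With the set term kept, 319 genes and 11 lists moved to 997 genes (413 and 584) and 18 lists with no low-count filter, and to 1536 genes (677 and 859) with DESeq2. Its 11 lists moved to 0 with an estimated correlation and 2 with fry. Leaving out 1 library gave 0 to 1633 genes, 0 to 579 higher, 0 to 1054 lower and 10 to 19 lists, and Ntn4 at −1.12 to −0.94, past the threshold without aged 3 or aged 5 but not in the other 7 such fits; the cause was not tested. The 2 genes left without young 4 were Rps2-ps10 and Rnps1-ps, and the 1 left without aged 2 was Xbp1. Limma-voom, RLE factors and removal of hemoglobin, immunoglobulin and mitochondrial genes gave 378, 278 and 335 genes, sharing 290, 276 and 315 with the 319.

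With a replicate block 13 genes were called, 6 higher and 7 lower. Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at 0.456, 0.554, −0.387 and 0.739, and young 1, young 3 and aged 3 did not correlate best with their own number.

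Reversed values follow for the Y-linked term, both terms, and young 1 to 3 against aged 5, in this order, as log2 fold changes: Marco −1.84, −1.97 and −1.61; Cxcl10 −0.18, −0.029 and −0.027; Ccl8 −0.29, −0.31 and −0.42; Ccl4 −0.45, −0.53 and −0.084; Car3 −0.38, −0.36 and −0.30; Lpl −0.55, −0.52 and −0.45. The mean of the adipocyte list was −0.41, −0.34 and −0.36, and that of the interferon list −0.44, −0.45 and −0.45. Gbp2 was at −0.020 and −0.057, and Adrb1 at −0.18 and −0.36, with the Y-linked term and both terms. Phospho1 was at 0.0015 with both terms and 0.0018 between young 1 to 3 and aged 5, and Pax5 at 0.63 in the 3-library set. Aged 5 alone sets the age effect in the fits with Y-linked terms or libraries; for Pax5 the cause was not tested. Depth limits low genes such as Gzmk, whose young level was 0.111 CPM.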

Other observations

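The genes and terms in this part, and its tests against other splits of the libraries, were chosen after the data were seen, and all come from the edgeR fit with the library set term unless said otherwise. Genes with the largest rises included Fcrl5, an Fc receptor-like gene of B cells, at 0.393 ± 0.235 CPM in young and 47.5 ± 67.8 in aged libraries (SD, n = 4 and 5), and Vsig4, a complement receptor gene of macrophages, at 1.34 ± 0.698 and 12.5 ± 7.12. Ctla4, an inhibitory T cell receptor gene, was at 0.217 ± 0.116 and 2.07 ± 1.20, and Cxcl13, a B cell-attracting chemokine gene, at 0.323 ± 0.266 and 13.2 ± 15.3. Myh3, the embryonic myosin heavy chain gene, was at 0.964 ± 0.524 and 10 ± 7.68. Genes with the largest falls included Cldn10, a claudin gene, at 4.59 ± 1.02 and 0.751 ± 0.395, Lrrc15 at 2.88 ± 0.83 and 0.598 ± 0.268, and Syt14 at 2.71 ± 0.369 and 0.292 ± 0.265. The edgeR adjusted p was 0.0405 to 0.0467 for these genes. Fcrl5 was also higher in libraries with Xist than in those with Y-linked transcripts beside set and age, by 6.33 on the log2 scale. That difference rests on aged 5 alone against aged 1 to 4, so it is given without a test.

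Among annotation terms of the 217 lower genes, DNA replication initiation held 8 of its 16 tested genes (hypergeometric adjusted p = 3.5e-08) and heme biosynthesis 6 of 15 (adjusted p = 2.6e-05). Among the 102 higher genes, the external side of the plasma membrane was the only term past the threshold, with 13 genes (hypergeometric adjusted p = 5.9e-04). The hypergeometric test treats genes as independent, and its p does not measure variation between mice. With the set term, members correlated at an estimated 0.52 in the cell division list and 0.97 in the erythroid list. The 217 and 102 genes put in also depended on single libraries. In the group-only fit 0 genes were called, so no term could be tested.

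Counts of calls were set against other splits of the libraries. For the 0 genes of the group-only fit the comparison says nothing, since each of the 100 splits drawn (100 of 100) must give as many. The highest other, 2005, put young 1 to 3, aged 2 and aged 5 on one side and so followed the library sets; several splits with many more calls than the real one point to a structure of the samples. For the 17 lists 26 of 100 splits gave as many, with a highest other of 26, so chance was not excluded. For the 319 genes with the set term 2 of 60 splits within the sets gave as many, the real one included. The other, young 1 to 4 with aged 3 against aged 1, 2, 4 and 5, gave 990. The share is under 0.05, but the set term was chosen after the data were seen, so chance was not excluded. The real split also nearly followed Xist and Y-linked transcripts, so the share says nothing of age apart from them. For the 11 lists with the set term 51 of 60 splits gave as many, with a highest other of 27, so chance was not excluded.

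In aged 3, 207 genes had exactly 1 count and 1677 had 1 to 9 counts, against 1838 to 2109 and 6135 to 6778 in the other 8 libraries.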
